A study of Arabidopsis thaliana with 18 samples.

How the data were processed

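RNA levels were measured in plant material of Arabidopsis thaliana on 18 single-colour Affymetrix arrays, 1 array per plant sample. Total RNA was extracted with a plant RNA kit, amplified and biotin-labelled with the One-Cycle kit. The arrays form 6 groups of 3 independent replicates: 2 genotypes, the accession Col-0 and the triple mutant tga2-5-6, by 3 treatments of 4 h, with 0.5% methanol in water (control), 75 µM phytoprostane A1 (PPA1) or 75 µM oxo-phytodienoic acid (OPDA). The labels do not name the organ sampled or the growth conditions.

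The deposited values are intensities on a linear scale, 1 per probe set and array, from 0.0678 to 41686. The mean left after trimming the lowest and highest 2% of the probe sets was the same on every array, so the authors had scaled each array to a common level. The submitters' processing notes name GCRMA, whose output is log2 and quantile-normalized; the deposited intensities are neither, and the algorithm that made them is not stated. Median intensity ran from 159 to 185 per array, and 14.4% to 18.0% of the probe sets lay below 16. Correlations of log2 values were 0.900 to 0.935 within groups and 0.868 to 0.926 between groups, and no pair among the 153 pairs of arrays was identical. The GAPDH 3'/5' control ratio ran from 0.871 to 1.99 per array. The actin 3'/5' ratio ran from 24.9 to 66.6, with a group mean of 48.3 ± 16.8 (SD, n = 3) in untreated tga2-5-6, 34.4 ± 11.7 in untreated Col-0, and 28.1 to 30.4 in the other groups. The number of arrays per group limits the precision.

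Values below 1 were set to 1 and log2-transformed. Of 22810 probe sets, 64 array controls were left out, and probe sets with a value of at least 16 on at least 3 arrays were kept, which left 21869. No further normalization was applied. The array's annotation gave 1 gene for 13513 probe sets, several genes for 503 and none for 8730; of the kept probe sets 12848 had 1 gene, for 12643 genes. Gene names come from the reference annotation TAIR10.1, matched through the gene identifier, and 77 probe sets with 1 gene had no current locus. All probe sets were tested, and only those with 1 gene are named.

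A group-means model was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, prior degrees of freedom 1.50, default moderation), and p-values were adjusted by Benjamini-Hochberg over the kept probe sets. A probe set passed with an adjusted p under 0.05 and a change of at least 2-fold. The 9 comparisons were PPA1 against control, OPDA against control and PPA1 against OPDA in each genotype, tga2-5-6 against Col-0 in control, and, for each compound, the response in tga2-5-6 minus that in Col-0 (genotype difference of the response). Tests are two-sided, errors of log2 differences are standard errors of the model, and intervals are 95% intervals not adjusted for the number of genes. On simulated data, with 200 of 21869 probe sets changed, changes of 2-fold were recovered in 17.9% to 31.3% of cases in the comparisons of groups and in 7.46% and 16.4% for the genotype differences; changes of 4-fold were recovered in 56.7% to 76.1% and in 46.3% and 44.8%. A call also required an estimated change of at least 2-fold, which by itself lowers the recovery of true 2-fold changes. The simulations gave 0 calls of wrong sign and 1 to 10 false calls per comparison.

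The 22 gene lists held TGA factors, tau-class and phi-class glutathione S-transferases, other xenobiotic detoxification, jasmonate biosynthesis, jasmonate response, salicylic acid response, heat shock, mitotic cell cycle, DNA replication, photosynthesis, tryptophan and indole glucosinolates, aliphatic glucosinolates, antioxidants, mitochondrial dysfunction, sulfate assimilation, endoplasmic reticulum stress, abscisic acid response, auxin response, senescence, root markers and constitutive reference genes. Only 66 of their 372 genes were measured, since many of the study's probe sets carried no gene name in the annotation. A gene counted as measured if a kept probe set was assigned to it alone. The 6 lists with at least 4 measured genes were tested with camera, preset correlation 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. Another 46 gene families were formed by symbol prefix (at least 5 genes), by a rule written after the annotation was seen and before any comparison was computed. The mutated genes TGA2, TGA5 and TGA6 had no named probe set, so the genotype labels could not be checked through them.

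The thresholds, tests, lists and alternatives above were set before the data were examined, and so was the rule for named genes: in each comparison the 5 highest and 5 lowest probe sets with 1 gene that passed and whose groups did not overlap, and up to 2 highest and 2 lowest passing members of each list, or the member with the largest change where none passed. Another choice, of the 5 highest and 5 lowest with a mean intensity of at least 500, was made after the values were seen. Of 180 named calls that passed, 162 were kept under every alternative setting and 120 also without each array in turn. Which of them the text gives was decided after the values were seen; those given held without each array unless the arrays their call rests on are named. Genes named for a genotype difference that passed only over a chosen set, and genes of the genotype comparison over all treatments, were also chosen after their values were seen.

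Alternatives were no filter on low values, no minimum change, a 3-fold minimum, an adjusted p under 0.01 and a filter at 64. Others were median centring, quantile normalization, a pseudocount of 16, a variance trend with robust moderation, array weights and a replicate block. Further ones were fits to the arrays of a comparison alone and leaving out each array. After the data were seen, a filter at 128 and a fit without Col-0 OPDA replicate 1 and tga2-5-6 control replicate 2, the arrays with the lowest correlation to their group, were added. Replicate numbers did not pair the arrays (correlations of residuals between equal numbers -0.05 to 0.07 over 45 pairs), so the fit is unpaired. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.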

Results

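RNA levels were measured on 18 arrays from Arabidopsis plants of the accession Col-0 and of tga2-5-6, a mutant in 3 TGA transcription factors, with 3 replicates for each genotype and treatment. Plants were treated for 4 h with PPA1, with OPDA or with the methanol solvent (control). OPDA is an enzymatic product of α-linolenic acid and the precursor of jasmonic acid; phytoprostanes such as PPA1 form from the same fatty acid without enzymes. Both are cyclopentenones, and PPA1 carries a side-chain hydroxyl group that OPDA lacks. The series asks which genes that respond to these compounds are regulated by TGA factors. After filtering, 21869 probe sets were compared. Before filtering, median intensities over all probe sets were 159 to 185 per array. Levels below are intensities as mean ± SD over 3 arrays and log2 differences are given ± SE. A gene's group mean under 16, the value of the filter, is given as below 16. Where a group's mean intensity or its mean on the log scale was under 16, the change is given as levels, since a log2 difference from it depends on noise near the floor.

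**Figure D1:**
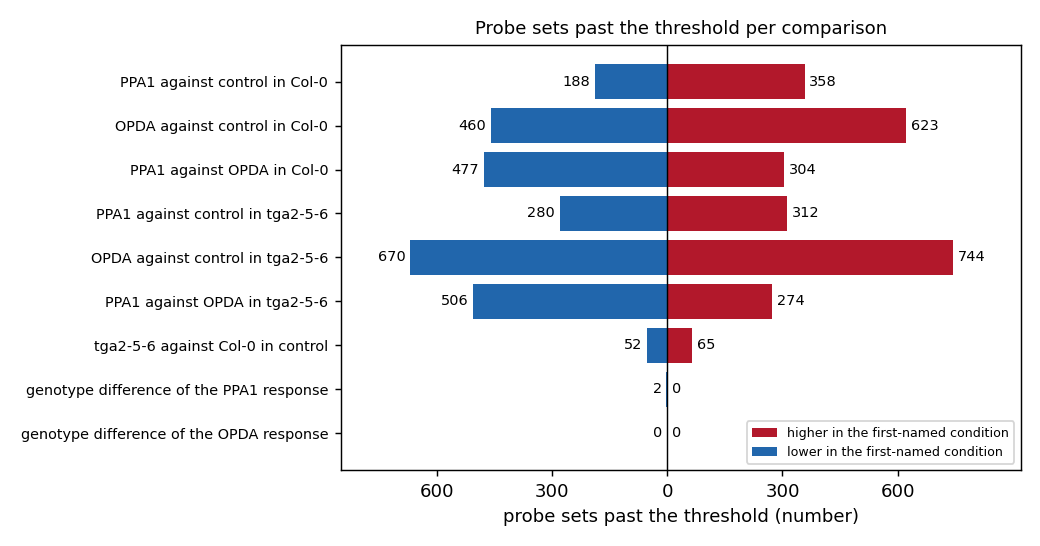
Horizontal bars give the number of probe sets past the threshold in each of the 9 comparisons, higher in the first-named condition to the right and lower to the left. For the genotype differences of a response, left means a smaller or more negative response in tga2-5-6. OPDA against control gave 1083 probe sets in Col-0 and 1414 in tga2-5-6, and the genotype differences gave 2 and 0.

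The response of the wild type to PPA1 was measured against the solvent. In Col-0, AT1G53540, which encodes the chaperone HSP17.6C, rose from 217 ± 49.0 to 7531 ± 5051 (log2 difference 4.89 ± 0.44, adjusted p = 4.3e-05). AT1G52560, another small heat shock protein, rose to 3405 ± 2785 from controls near 16, which leave the size of its change inexact in every comparison with control. The aldo-keto reductase AT1G60750 rose from below 16 to 627, and the glycosyltransferase UGT73B4 by 5.48 ± 0.74. The tau-class glutathione S-transferases GSTU25 and GSTU22, which conjugate electrophiles to glutathione, rose by 4.74 ± 0.44 and 3.70 ± 0.30, GSTU25 from 255 ± 67.2 to 6659.8 ± 734. Among those that fell were AT5G66815 (from 54.3 to below 16), the cytochrome P450 CYP718 (from 133 to below 16), the peroxidase AT5G19890 (-3.46 ± 0.65) and the phi-class glutathione S-transferase ATGSTF13 (-2.53 ± 0.48). Of 7 measured genes of the heat shock list 6 rose and 1 did not pass (also 6 adjusted over the list alone; list median 2.66, camera adjusted p = 4.7e-11). Of 5 detoxification genes 3 rose, UGT73B4, UGT73B5 (3.77 ± 0.36) and the alkenal reductase AER (4.61-fold), and 4 adjusted over the list alone (list mean 2.71, adjusted p = 6.7e-09). Of 11 tau-class glutathione S-transferases 2 rose and 9 did not pass (2 rose and 1 fell adjusted over the list alone). Their median was -0.52, their mean 0.58, and the test pointed up with an adjusted p of 0.491. No measured jasmonate-response gene passed, with THI2.1, a thionin, at 16.2 ± 12.8 in control and 29.2 ± 3.19 with PPA1 (adjusted p = 0.447; list median -0.48, camera adjusted p = 0.948). In total 546 probe sets passed, 358 higher and 188 lower. Without Col-0 PPA1 replicate 3 the count was 351, and in the fit to the arrays of this comparison alone 221.

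OPDA was compared with the same solvent controls. In Col-0, JRG21, a dioxygenase of the jasmonic acid oxidase family, rose from below 16 to 4119.7 ± 789 (adjusted p = 0.00363), and its relative AT2G38240 from 88.6 ± 39.2 to 8229 ± 755 (6.65 ± 0.72). UGT76E12, a glycosyltransferase, rose from below 16 to 1206 and AT1G52560 to 1224. THI2.1 rose from 16.2 ± 12.8 to 193, and OPCL1, which activates a jasmonate precursor, by 1.84 ± 0.27. GRX480, a glutaredoxin that binds TGA factors, rose by 3.77 ± 0.69, the auxin-conjugating enzyme GH3.3 by 2.55 ± 0.25, and the tryptophan-pathway gene AT2G04400 by 2.08 ± 0.23. The zinc-finger gene STZ rose 4.29-fold. Among those that fell were the cell-wall gene XTH26 (from 115 to below 16) and AT4G03500 (from 87.2 to below 16), and among intensities of at least 500 PR-1-LIKE (-2.73 ± 0.51) and XTH19 (-2.50 ± 0.30). In the heat shock list 4 of 7 genes rose and 3 did not pass, as over the list alone (median 1.46, adjusted p = 6.8e-05, but adjusted p = 0.0694 with an estimated correlation). In the jasmonate-response list 1 of 4 rose, THI2.1, and 2 adjusted over the list alone (median 3.07, adjusted p = 0.00900, but adjusted p = 0.0694 with an estimated correlation). In the detoxification list 2 of 5 rose, UGT73B4 (3.53 ± 0.74) and UGT73B5, and 2 over the list alone (median 1.04, adjusted p = 0.00121). Without Col-0 control replicate 3, Col-0 OPDA replicate 2 or Col-0 OPDA replicate 3 only 1 rose. In the tau class 3 of 11 rose, among them GSTU25 (3.58 ± 0.44) and GSTU26 (3.45 ± 0.30), and 1 fell (3 and 2 adjusted over the list alone). The fall was lost without Col-0 control replicate 1 or 3 or Col-0 OPDA replicate 2 or 3. The class had a median of -0.14, a mean of 0.45 and an upward test with an adjusted p of 0.135. In total 1083 probe sets passed, 623 higher and 460 lower. The median log2 difference of all probe sets was -0.12, and with arrays centred on their medians 716 were higher and 327 lower (662 and 371 after quantile normalization).

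Setting PPA1 against OPDA at the same dose and time asks where the compounds differ. In Col-0, AT2G38240 stood at 40.3 ± 21.0 with PPA1 and 8229 ± 755 with OPDA (-7.86 ± 0.72, adjusted p = 2.5e-05). AT3G28220, which encodes a TRAF-like protein, stood below 16 with PPA1 and at 2674 with OPDA, and the lipase-like gene AT1G54020 below 16 and at 1768. OPCL1, the single measured jasmonate-biosynthesis gene (-2.09 ± 0.27), GH3.3 (-2.19 ± 0.25), the ATP sulfurylase APS3 (-1.34 ± 0.23) and the glucosinolate gene UGT74B1 (-1.17 ± 0.19) were lower too. Higher with PPA1 were AT4G36610, which encodes an alpha/beta hydrolase, at 1675 ± 356 against 114 ± 45.8 (3.93 ± 0.44), UGT73B5 (2.21 ± 0.36), AER (1.29 ± 0.22) and the mitochondrial chaperone gene AT5G51440 (1.43 ± 0.28). Within the tau class the compounds parted: GSTU22 was higher with PPA1 (2.13 ± 0.30) and GSTU26 higher with OPDA (-4.46 ± 0.30), 1 gene each way of 11, also over the list alone. Some genes that rose with both compounds did not pass for the difference between them, though for GSTU25 the interval lay above 0 and for AT1G52560 it was wide. For NDB2, a mitochondrial NADH dehydrogenase, the difference was 0.14 (95% interval -0.28 to 0.57), for AT1G52560 0.98 (-1.31 to 3.27), and for GSTU25 1.16 (0.21 to 2.12, adjusted p = 0.180). Of 7 heat shock genes 1 was higher with PPA1, and 3 adjusted over the list alone (median 1.12, adjusted p = 0.00198, but adjusted p = 0.179 with an estimated correlation). Without Col-0 PPA1 replicate 1, 3 were higher. Of 5 detoxification genes 2 were higher, and 3 over the list alone (median 1.29, adjusted p = 0.00180). No jasmonate-response gene passed alone and 2 were lower over the list alone, with a list median of -2.73 (adjusted p = 0.00482, but adjusted p = 0.0546 with an estimated correlation). Past the threshold 781 probe sets differed, 304 higher and 477 lower with PPA1. The responses to PPA1 and OPDA shared 150 raised probe sets against 10.2 expected for independent lists, and 74 lowered ones against 3.95, while 12 went opposite ways. These responses share their 3 control arrays, which alone gave a correlation across probe sets of 0.50 in simulation, as large as the observed 0.50, while the covariance was 0.35 against 0.19 simulated. At most 1 shared call arose in a simulation, but all simulated probe sets were unchanged, so few calls could arise at all. The simulation therefore cannot tell how many of the 150 and 74 shared calls come from the shared controls. The 74 shared falls became 37 without Col-0 control replicate 1, 48 without Col-0 control replicate 3, 47 without Col-0 PPA1 replicate 2 and 49 without Col-0 PPA1 replicate 3.

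The same treatments were measured in the mutant. In tga2-5-6, PPA1 raised the small heat shock genes AT1G52560 (from 18.1 to 5753), ATHSP22.0 (7.96 ± 0.85), AT2G29500 (4.73 ± 0.26) and AT1G53540, which went from 171 ± 57.7 to 11446 ± 2261 (6.10 ± 0.44, adjusted p = 1.0e-05). UGT73B4 rose from below 16 to 263 and NDB2 by 1.31 ± 0.20, and UGT73B5 rose 3.99-fold and GSTU22 4.01-fold. Among those that fell were AT5G33250 (from 36.2 to below 16) and AT4G35200 (from 49.6 to below 16), and among intensities of at least 500 AT5G10130 (-3.18 ± 0.54) and the peroxidase AT3G49960 (-2.55 ± 0.45). Of 7 heat shock genes 6 rose (median 3.81, adjusted p = 8.2e-15), and of 5 detoxification genes 2 rose (median 0.91, adjusted p = 0.00136), with the same numbers adjusted over the lists alone. In the tau class 1 of 11 rose, GSTU22 (2 rose and 1 fell adjusted over the list alone; list adjusted p = 0.296). There were 2 that rose without tga2-5-6 control replicate 2 or tga2-5-6 PPA1 replicate 3, while 1 fell without tga2-5-6 PPA1 replicate 1. No jasmonate-response gene passed, with the regulator ORA47 at -1.26 ± 0.56 (adjusted p = 0.224). Over all probe sets 592 passed, 312 higher and 280 lower. The GAPDH and actin 3'/5' ratios were 0.953 ± 0.0721 and 29.4 ± 3.47 with PPA1 against 1.55 ± 0.471 and 48.3 ± 16.8 in control, and in Col-0 1.14 ± 0.394 and 28.7 ± 3.21 against 1.26 ± 0.107 and 34.4 ± 11.7. The count was 361 without tga2-5-6 PPA1 replicate 1 and 369 without tga2-5-6 control replicate 1. It was 94 in the fit to the arrays of this comparison alone, which borrows no spread from the other groups. The median of all probe sets was -0.13, and the split was 386 higher and 226 lower with median centring and 362 and 175 after quantile normalization.

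OPDA in tga2-5-6 raised JRG21 from 38.0 ± 59.8 to 4335 ± 495 (adjusted p = 0.00399), the carboxypeptidase-like gene scpl30 from below 16 to 1028, AT1G52560 from 18.1 to 1546, ATHSP22.0 by 6.64 ± 0.85 and the calmodulin-like gene AT1G76640 by 6.10 ± 1.30. OPCL1 rose by 1.75 ± 0.27, GRX480 by 3.57 ± 0.69, UGT73B4 from below 16 to 97.9, NDB2 by 1.65 ± 0.20, APS3 by 1.36 ± 0.23 and AT2G04400 by 1.62 ± 0.23. Lower were AT2G37820 (from 62.9 to below 16), AT4G11000 (from 95.8 to below 16) and the auxin-conjugating gene WES1 (-1.41 ± 0.27). In the tau class 2 of 11 rose, GSTU26 (3.95 ± 0.30) and GSTU16 (1.59 ± 0.30), and 1 fell, a call lost without any 1 of the 6 arrays. The class had a median of -0.18, a mean of -0.02 and an upward test with an adjusted p of 0.357. Of 7 heat shock genes 5 rose (median 2.01, adjusted p = 1.6e-07, but adjusted p = 0.0640 with an estimated correlation). Of 4 jasmonate-response genes 2 rose, THI2.1 and JMT (median 3.27, adjusted p = 0.0266, but adjusted p = 0.109 with an estimated correlation). The list's adjusted p was 0.0522 with median centring. Neither of these 2 genes passed without tga2-5-6 control replicate 1 or 3 or tga2-5-6 OPDA replicate 1 or 3, 1 passed without tga2-5-6 OPDA replicate 2, and the list's adjusted p was 0.0626 without tga2-5-6 control replicate 1. Of 5 detoxification genes 1 rose, UGT73B4, with a list median of 0.36 and an adjusted p of 0.231. Adjusted over the lists alone, the heat shock, jasmonate-response, detoxification and tau-class counts were the same. Over all probe sets 1414 passed, 744 higher and 670 lower. The median of all probe sets was -0.17, and the split was 826 higher and 474 lower with median centring and 853 and 432 after quantile normalization.

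The compounds were compared in the same way in tga2-5-6. AT3G28220 (-6.80 ± 1.22), scpl30 (below 16 against 1028), AT1G54020 (-5.57 ± 1.09), GSTU26 (-3.94 ± 0.30), OPCL1 (-1.54 ± 0.27) and GH3.3 (-1.47 ± 0.25) were lower with PPA1. Higher with PPA1 were AT4G11000 (155 against below 16), AT2G44370 (11.3-fold), the transcription factor gene WRKY53 (2.52 ± 0.25), GSTU22 (1.98 ± 0.30) and AT5G51440 (1.71 ± 0.28). AT2G38240 stood at 287 ± 198 with PPA1 and 9037 ± 818 with OPDA. For AT1G52560 the difference was 1.87 (95% interval -0.42 to 4.16, adjusted p = 0.427) and for NDB2 -0.34 (-0.76 to 0.09, adjusted p = 0.441). Of 7 heat shock genes 2 were higher with PPA1, and 4 over the list alone (median 1.33, adjusted p = 4.7e-04, but adjusted p = 0.107 with an estimated correlation). Without any 1 of tga2-5-6 OPDA replicates 1, 2 and 3 and tga2-5-6 PPA1 replicates 1 and 3 the count was 1. Of 4 jasmonate-response genes 1 was lower, and 2 over the list alone (median -3.14, adjusted p = 0.00427, but adjusted p = 0.0842 with an estimated correlation). That count was 0 without any 1 of the same 5 arrays. Of 5 detoxification genes 1 was higher (median 0.56, adjusted p = 0.0294, but adjusted p = 0.0855 with an estimated correlation). The 1 was lost without tga2-5-6 OPDA replicate 2 or 3 or tga2-5-6 PPA1 replicate 3. The list's adjusted p was 0.0531, 0.0567 and 0.0596 without tga2-5-6 OPDA replicate 1, tga2-5-6 PPA1 replicate 1 and tga2-5-6 PPA1 replicate 2. Past the threshold 780 probe sets differed, 274 higher and 506 lower with PPA1. The PPA1 and OPDA responses in tga2-5-6 shared 146 raised probe sets (10.6 expected) and 115 lowered ones (8.58 expected), and 9 went opposite ways. The expected numbers are for independent lists, while these responses share the mutant's 3 control arrays. The correlation was 0.58 against 0.50 simulated for shared controls alone and the covariance 0.45 against 0.19. No shared call arose in the simulations, but their probe sets were all unchanged and few could pass. How many shared calls come from the shared controls thus cannot be told.

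The genotypes were compared without compound. In control plants the mutant had lower levels of URE, the urease gene (17.1 ± 12.4 against 142 ± 16.5 in Col-0, adjusted p = 0.00823), and of the organic cation transporter OCT5 (-2.34 ± 0.27), at 337 ± 42.4 in Col-0 and 70.0 ± 25.9 in the mutant. It also had lower levels of AT4G13180 (-2.23 ± 0.29) and AT5G05960 (-1.57 ± 0.18), and higher levels of ECS1 (8.01-fold) and AT2G25510 (2.59 ± 0.17). GSTU25 was the single tau-class gene of 11 that passed (2 over the list alone), at 54.3 ± 29.7 in the mutant and 255 ± 67.2 in Col-0 (-2.41 ± 0.44). Its call was lost without Col-0 control replicate 1, 2 or 3. The class had a median of -0.33 (adjusted p = 0.0235, but adjusted p = 0.0633 with an estimated correlation), and its adjusted p was 0.0564 without Col-0 control replicate 1 and 0.0733 without tga2-5-6 control replicate 1. AER was the single detoxification gene of 5 that passed (-1.19 ± 0.22; 1 higher and 2 lower over the list alone), a call lost without Col-0 control replicates 2 or 3 or any 1 of the mutant's control arrays. The list's median was -0.76 with an adjusted p of 0.125, and 0.0401 without Col-0 control replicate 3. AT2G29500 was the single heat shock gene of 7 that was lower (-1.52 ± 0.26), lost without Col-0 control replicate 1 or 2 or any 1 of the mutant's control arrays. The heat shock list had a median of -0.37 (adjusted p = 0.0418, but adjusted p = 0.414 with an estimated correlation and 0.0537 with median centring). Its adjusted p was 0.0999, 0.0543, 0.119 and 0.0568 without Col-0 control replicate 1, Col-0 control replicate 2, tga2-5-6 control replicate 1 and tga2-5-6 control replicate 2. Over all probe sets 117 differed, 65 higher and 52 lower in the mutant, but only 6 in the fit to the arrays of this comparison alone. The split was 50 higher and 52 lower with median centring and 57 and 64 after quantile normalization. The count was 67, 67 and 43 without Col-0 control replicates 1, 2 and 3, and 57 and 73 without tga2-5-6 control replicates 1 and 2. The untreated mutant arrays also had the highest actin 3'/5' ratio, 48.3 ± 16.8 against 34.4 ± 11.7 in untreated Col-0.

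The question of the series is which responses differ in the mutant. In Col-0, AER rose with PPA1 from 1063 ± 306 to 4770.0 ± 490.4, while in tga2-5-6 it stood at 455 ± 43.7 in control and 405 ± 40.3 with PPA1 (genotype difference of the response -2.37 ± 0.31, adjusted p = 0.0363). AT1G14130, which encodes the auxin-oxidizing dioxygenase DAO1, went from 261 ± 52.2 to 947 ± 105 with PPA1 in Col-0 and from 263 ± 78.2 to 205 ± 33.3 in the mutant (-2.20 ± 0.29, adjusted p = 0.0363). With OPDA it rose in both genotypes, by 2.13 ± 0.21 and 1.84 ± 0.21. These were the only 2 probe sets of 21869 whose PPA1 response differed past the threshold in limma. In all 1617 had an unadjusted p under 0.05, 1096 of them with a negative difference. Both calls were lost with quantile normalization (adjusted p = 0.0582 for AER and 0.0606 for AT1G14130), and AER also with a replicate block (0.0861). Over 6 alternative settings tested for these genes adjusted p ran from 2.2e-04 to 0.0861 for AER and from 4.0e-04 to 0.0606 for AT1G14130. The fit to the arrays of this comparison alone gave 0 probe sets, so both calls were lost there too. No probe set passed without Col-0 control replicate 3, any 1 of the 3 Col-0 PPA1 arrays, or tga2-5-6 PPA1 replicate 1 or 3. AER also did not pass without tga2-5-6 control replicate 1 or 3, nor AT1G14130 without Col-0 control replicate 1 or tga2-5-6 control replicate 3. Without single arrays their adjusted p reached 0.167. The count was 7 without tga2-5-6 PPA1 replicate 2 and 5 without tga2-5-6 control replicate 2, 18 with a pseudocount of 16, 31 with a variance trend and robust moderation, and 16 with a filter at 128. Of the 358 probe sets raised by PPA1 in Col-0, 173 were also raised in tga2-5-6, and 96 (26.8%) had a smaller response in the mutant when the genotype difference was adjusted over this set alone, a set chosen in Col-0. Of the 312 raised in the mutant, 10 (3.21%) had a smaller response in Col-0. Counted without a test, 270 of the 358 (75.4%) had a smaller response in the mutant, and 227 of the 312 (72.8%) a smaller one in Col-0. The 96 became 58 without Col-0 PPA1 replicate 3. Among them were AT4G36610, at 1675 ± 356 with PPA1 in Col-0 and 116 ± 73.4 in the mutant (-3.98), AT5G16980, the paralogue of AER (-3.27), the trypsin inhibitor gene AT1G17860 (-2.07), GSTU25 (-3.11), UGT73B5 (-1.77), GSTU22 (-1.69) and OCT5 (-1.86). When adjusted over all probe sets none of these passed with the main settings, with adjusted p from 0.114 upward, nor with quantile normalization. AT4G36610, AT5G16980 and AT1G17860 passed with the pseudocount, with the variance trend and robust moderation, and with the filter at 128. GSTU25 passed with the pseudocount (limma adjusted p = 0.0141) and OCT5 with the trend (0.0419). UGT73B5 and GSTU22 passed in none of these. GSTU25 stood at 158 ± 83.1 with PPA1 in the mutant. The tau-class list did not pass for the genotype difference of the PPA1 response, nor did any of its 11 genes over all probe sets with the main settings. UGT73B4 rose in both genotypes, to 1077 ± 241 with PPA1 in Col-0 and 263 ± 55.6 in the mutant, whose control level was below 16.

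**Figure D2:**
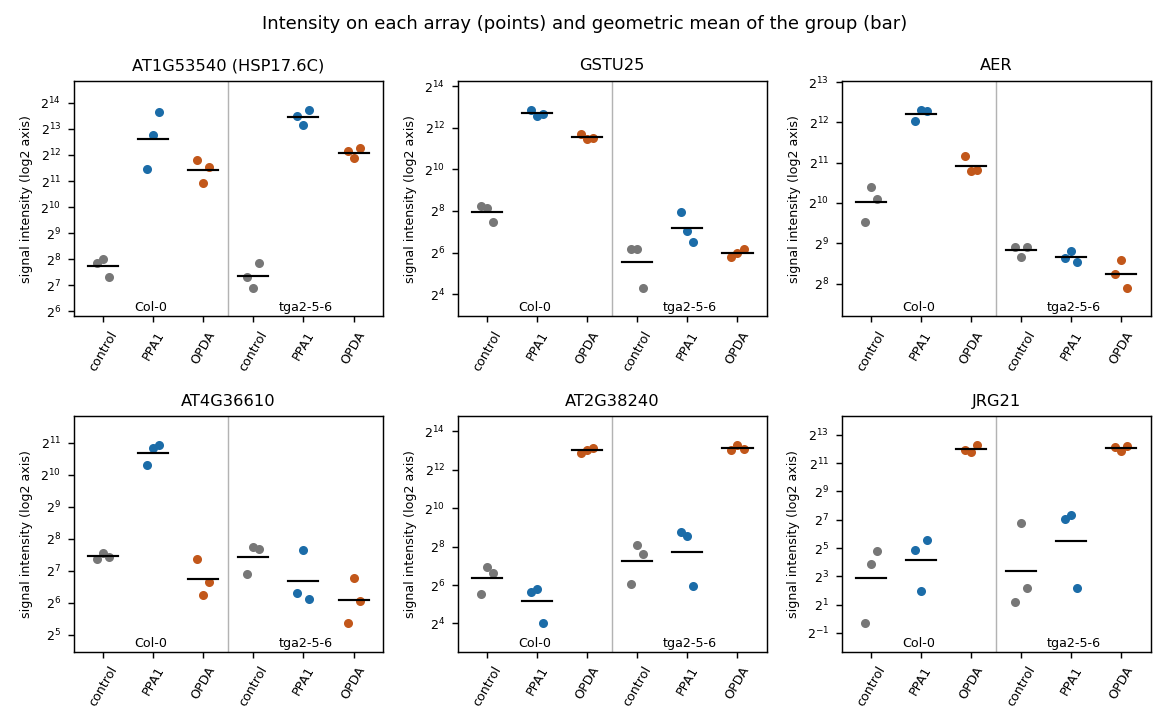
Signal intensity on a log2 axis of 6 genes on each array (points) and the geometric mean of each group (bars), for control, PPA1 and OPDA in Col-0 (left) and tga2-5-6 (right). AER, GSTU25 and AT4G36610 stood at 405, 158 and 116 on average with PPA1 in the mutant against 4770.0, 6659.8 and 1675 in Col-0. With OPDA these genes stood at 308, 64.1 and 73.0 in the mutant against 1954, 2968 and 114 in Col-0. The OPDA levels of AT2G38240 and JRG21 were 9037 and 4335 in the mutant against 8229 and 4119.7 in Col-0.

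The detoxification list had a smaller PPA1 response in the mutant (median difference -0.79, adjusted p = 0.00697, but adjusted p = 0.0545 with an estimated correlation). AER passed, and 2 of 5 members did over the list alone. Its adjusted p was 0.0617 without Col-0 control replicate 3 and 0.0553 without tga2-5-6 control replicate 3, and the call of AER was lost in the fits without single arrays given before. The heat shock list had a larger PPA1 response in the mutant (median difference 1.21, adjusted p = 1.5e-04, but adjusted p = 0.123 with an estimated correlation), with no member past the threshold and 2 over the list alone. For OPDA the heat shock list had a median difference of 1.03 (adjusted p = 0.00124, but adjusted p = 0.201 with an estimated correlation). No OPDA response of a probe set differed between the genotypes past the threshold in limma, with 1419 probe sets at an unadjusted p under 0.05. With other settings 7 passed with a pseudocount of 16, 2 without the pair of arrays with the lowest correlations, and 1, 2, 1, 2 and 3 without Col-0 OPDA replicate 2, Col-0 OPDA replicate 3, tga2-5-6 control replicate 1, tga2-5-6 control replicate 3 and tga2-5-6 OPDA replicate 3. Of the 623 probe sets raised by OPDA in Col-0, 477 were also raised in the mutant and 19 (3.05%) had a smaller response there over the set alone. OPCL1 differed by -0.09 between the genotypes in its OPDA response (95% interval -0.91 to 0.73), and AER by -1.50 (-2.16 to -0.83, adjusted p = 0.371). GSTU25 differed by -3.13 in its OPDA response (limma adjusted p = 0.371), against -3.11 for PPA1. With a pseudocount of 16 its OPDA difference passed (limma adjusted p = 0.0371). The 19 became 4, 12, 7, 11, 12 and 7 without Col-0 control replicate 2, Col-0 OPDA replicate 1, Col-0 OPDA replicate 2, tga2-5-6 control replicate 1, tga2-5-6 control replicate 2 and tga2-5-6 OPDA replicate 3. Of the probe sets lowered in Col-0, 9 of 188 for PPA1 and 3 of 460 for OPDA had a smaller fall in the mutant. The 9 became 25, 34 and 24 without Col-0 PPA1 replicates 1, 2 and 3. The 3 became 17, 8 and 13 without Col-0 OPDA replicates 1, 2 and 3, 7 and 5 without Col-0 control replicate 2 and tga2-5-6 control replicate 3, and 0 without Col-0 control replicate 1 or 3, tga2-5-6 control replicate 1 or 2 or tga2-5-6 OPDA replicate 1. Of the 280 probe sets lowered by PPA1 in the mutant 65 (23.2%) had a smaller fall in Col-0, but 4 of 175 (2.29%) after quantile normalization.

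**Figure D3:**
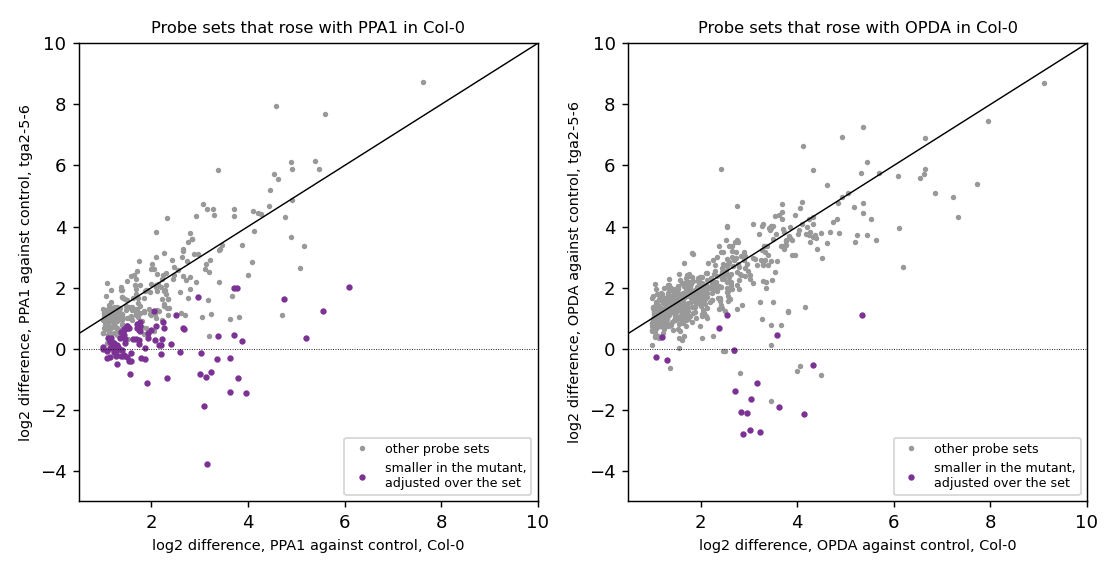
Each point is a probe set raised in Col-0 by PPA1 (left, 358) or OPDA (right, 623), with its log2 difference from control in Col-0 on the horizontal axis and in tga2-5-6 on the vertical axis. The diagonal marks equal responses and purple marks a smaller response in the mutant, adjusted over the set. The purple points number 96 for PPA1 and 19 for OPDA, and the medians were 1.72 in Col-0 and 1.11 in the mutant for PPA1 and 1.85 and 1.68 for OPDA. A set chosen in 1 genotype tends to respond less in the other. For probe sets chosen as raised in the mutant, the medians were 1.65 in the mutant and 1.34 in Col-0 for PPA1. For OPDA they were 1.72 and 1.52.

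Among the lists too small to test, GRX480 was the 1 of 2 salicylic-acid response genes that passed, with OPDA in both genotypes and with PPA1 (3.11 ± 0.69 in Col-0, 2.60 ± 0.69 in the mutant). The PPA1 calls were lost without Col-0 control replicate 3 or any 1 of the Col-0 PPA1 arrays, and in the mutant without tga2-5-6 control replicate 1 or 3 or any 1 of its PPA1 arrays. NDB2 was the 1 of 3 mitochondrial-dysfunction genes that rose in all 4 comparisons with control (1.94 ± 0.20 with PPA1 in Col-0). Of 2 sulfate-assimilation genes, APS3 (1.47 ± 0.23) and the sulfite reductase gene SIR rose with OPDA in Col-0, SIR not without Col-0 control replicate 1. APS3 also rose with OPDA in the mutant, where 2 passed without tga2-5-6 control replicate 2 or tga2-5-6 OPDA replicate 3. UGT74B1, 1 of 3 genes of aliphatic glucosinolates, rose with OPDA in Col-0 (1.28 ± 0.19), and in the mutant too, a call lost without tga2-5-6 control replicate 1 or tga2-5-6 OPDA replicate 1 or 3. STZ, 1 of 2 antioxidant-list genes, rose with OPDA in both genotypes, in the mutant not without tga2-5-6 control replicate 1. With PPA1, STZ was 1.34 ± 0.44 in Col-0, where it did not pass, and 1.71 ± 0.44 in the mutant, where it passed but not without any 1 of tga2-5-6 control replicates 1 and 3 and the 3 PPA1 arrays. In the auxin list of 3 genes, GH3.3 rose with OPDA in both genotypes, in the mutant not without tga2-5-6 control replicate 2 or tga2-5-6 OPDA replicate 1. In the mutant WES1 fell with OPDA and IAA29 with PPA1 (from 34.9 to below 16), a call of IAA29 lost without any 1 of the 6 arrays compared. The expansin gene EXPA7, 1 of 2 root markers, fell with PPA1 in Col-0 (-2.57 ± 0.55), with -2.21 and an adjusted p of 0.0927 without Col-0 control replicate 1. OPCL1 and AT2G04400 were the single measured genes of the jasmonate-biosynthesis and tryptophan lists. ATGSTF13, 1 of 2 phi-class genes, passed for PPA1 against control in Col-0 and in no other comparison. It did so for PPA1 against OPDA without Col-0 PPA1 replicate 1. No measured gene of the mitotic (3), DNA replication (1), endoplasmic reticulum stress (2) and abscisic acid (1) lists passed in any of the 9 comparisons. With fewer arrays 1 passed without tga2-5-6 PPA1 replicate 3 for the mitotic list, without tga2-5-6 control replicate 3 or tga2-5-6 PPA1 replicate 2 for the endoplasmic reticulum list, and without tga2-5-6 control replicate 2 for the abscisic acid list. No TGA factor (0 of 10) or senescence gene (0 of 8) had a kept probe set assigned to it alone, so their levels are not known. Of the 7 photosynthesis and 4 reference genes none passed either. The photosynthesis list's lowest adjusted p was 0.0623, with OPDA in the mutant, where its median was -0.50. That list passed without tga2-5-6 OPDA replicate 1 (0.0338) or 2 (0.0467), and for OPDA in Col-0 without Col-0 OPDA replicate 1. With an estimated correlation the calls that held were heat shock and detoxification for PPA1 against control in both genotypes, and detoxification for OPDA against control and PPA1 against OPDA in Col-0.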

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

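The test that asked whether the lower control level of the heat shock genes in the mutant accounts for their larger response, and the division of the splits by whether treated arrays were mixed, were chosen only after the result was seen. Responses to a compound that differed between the genotypes by the test of that difference are given here. AER had a PPA1 response lower in tga2-5-6 than in Col-0 by a log2 difference of -2.37, and AT1G14130 by -2.20 (adjusted p = 0.0363 for both). The detoxification list, with a median difference of -0.79, had a smaller PPA1 response in the mutant, and the heat shock list a larger response to PPA1 (1.21) and to OPDA (1.03), by the test with a preset correlation. With an estimated correlation none of the 3 passed (adjusted p = 0.0545, 0.123 and 0.201). Adjusted over the responsive set alone, 96 of 358 probe sets raised by PPA1 in Col-0, 9 of 188 lowered by PPA1, 19 of 623 raised by OPDA and 3 of 460 lowered by OPDA had a smaller response in the mutant.

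The first pattern is the smaller PPA1 response in tga2-5-6 of probe sets raised by PPA1 in Col-0. A constant shift of whole arrays is argued against. With each array centred on its median 84 of 385 (21.8%) still had a smaller response in the mutant. Of those raised in the mutant 10 of 386 (2.59%) were then smaller in Col-0. Centring removes a constant shift only. After quantile normalization the numbers were 80 of 371 (21.6%) and 12 of 362 (3.31%). Selection on noisy Col-0 arrays and low-intensity noise remain open. Probe sets were chosen without Col-0 PPA1 and control replicate 1, 2 or 3. For each probe set the response of the left-out Col-0 arrays was subtracted from that of the mutant. The median of these differences was -0.0835, -0.40 and -0.81. Over probe sets with a mean intensity of at least 500 the median difference was 0.0856, -0.27 and -0.58. The left-out Col-0 arrays had median responses of 1.34, 1.76 and 2.23, and the mutant 1.13, 1.18 and 1.21. Of the chosen probe sets 52.7%, 67.6% and 83.0% had a smaller response in the mutant, and of the bright ones 45.2%, 63.3% and 80%. The differences thus varied with the Col-0 replicate, and how much of the pattern the selection made cannot be told. For probe sets that fell the direction depended on the scaling: 9 of 188 (4.79%) chosen in Col-0 against 65 of 280 (23.2%) chosen in the mutant as deposited, 8 of 146 (5.48%) against 55 of 226 (24.3%) with median centring, and 24 of 183 (13.1%) against 4 of 175 (2.29%) after quantile normalization, so they do not decide it. Chance could not be excluded, with 8 of 100 splits giving as large a share as the real 26.8% and a highest other share of 55.1%, the 7 others all among the 12 that kept the PPA1 groups whole (at most 13.9% in the 87 that mixed them). Loss of the TGA factors is a biological explanation that the design names and that stays untested, as no other mutant was measured.

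The other pattern is the larger heat shock response in tga2-5-6. A lower control level in the mutant as the only cause cannot be told apart from a larger induction: in the PPA1-treated arrays 6 of 7 genes were higher in the mutant, by a median of 0.84 (camera adjusted p = 0.0464, and 0.427 with an estimated correlation), but by 0.48, with 5 of 7 higher, without Col-0 PPA1 replicate 1, and the mean log2 levels of the list overlapped between the genotypes (10.8, 11.7 and 12.4 in Col-0, 12.4, 12.1 and 12.7 in the mutant). AT4G21870, the member that was lower with PPA1, differed by -0.81 (limma adjusted p = 0.0456), and the others had an adjusted p from 0.155 to 0.866. It was also lower in the mutant with OPDA (-0.47) and in control (-0.76). In OPDA-treated arrays 5 of 7 genes were higher in the mutant, with a list median of 0.67 (camera adjusted p = 0.156). Whether 1 deviating array accounts for part of it cannot be told apart from a genotype effect with 3 arrays per group: without Col-0 PPA1 replicate 1 the median genotype difference was 0.63 against 1.21 with all arrays. A difference in RNA quality stays open, as the GAPDH 3'/5' ratio was 1.55 ± 0.471 in control and 0.953 ± 0.0721 with PPA1 in the mutant (1.26 ± 0.107 and 1.14 ± 0.394 in Col-0), and so does, untested, loss of the TGA factors.

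For the genotype differences of the responses, 100 of the 200 possible splits that exchange genotype names within a treatment were drawn. For PPA1, 14 of them gave at least 2 probe sets, the highest other 639, and 8 gave at least 2 lists, the highest other 3. For OPDA the real count of probe sets was 0, which every split reaches, so the splits cannot judge it. The highest other count was 14. At least 1 list was given by 38 splits, the highest other 3, and 6 gave as large a share as 3.05%, the highest other 24.7%. By the remaining counts chance cannot be excluded for any of them. The split with 639 probe sets exchanged the genotype names on the PPA1 arrays only, and so points to a structure of the samples, the difference between the genotypes that is seen across treatments. Splits that keep the treated groups whole carry that difference: they were 11 of the 13 others with at least 2 probe sets for PPA1, 5 of the 7 others with at least 2 lists, and all 5 others with as large a share for OPDA (at most 2.56% in the 85 that mixed the OPDA arrays). Mixed splits in turn add the genotype difference to the spread within groups, so neither kind shows chance alone, and the question stays open.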

How the results depend on the processing

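The filter at 128 and the fit without Col-0 OPDA replicate 1 and tga2-5-6 control replicate 2 were chosen only after the data were seen. Of 273 counts under alternative settings 196 stayed within 1.5 times the reported count. Of 1824 values of named genes under the 6 settings run for them 1775 kept direction and call, 35 lost and 11 gained the call. The cause was not tested for any change below except for thresholds and for fits with fewer arrays, whose construction changes how many probe sets can pass. Values are counts for, in order, PPA1 in Col-0, OPDA in Col-0, PPA1 against OPDA in Col-0, PPA1, OPDA and PPA1 against OPDA in the mutant, and the genotypes in control; shares are counts of probe sets with a smaller response in the mutant. With no minimum change they were 1832 for OPDA in Col-0, 985, 2642 and 1218 in the mutant, with 0 for the share of OPDA falls and 148 for shared falls. With a 3-fold minimum they were 290, 579, 411, 312, 720, 397 and 69, with shares of 53 (PPA1 rises) and 5 (OPDA falls) and overlaps of 78 and 35. With an adjusted p under 0.01 they were 300, 691, 490, 265, 838, 475 and 30, 0 for the PPA1 genotype difference, shares of 6 (OPDA rises) and 6 (OPDA falls), and overlaps of 88 and 32. Fits to the arrays of a comparison alone gave 221 for PPA1 and 484 for PPA1 against OPDA in Col-0, 94, 718 and 356 in the mutant, 6 for the genotypes, 0 for the PPA1 genotype difference, and shares of 10 (OPDA rises) and 0 (OPDA falls). For the PPA1 genotype difference the count was 4 with a filter at 64, 0 with quantile normalization, 18 with a pseudocount of 16, 31 with a variance trend and robust moderation, 1 with a replicate block, 16 with a filter at 128 and 9 without the pair of arrays. For OPDA it was 7 with the pseudocount and 2 without the pair, where the genotypes in control gave 67. The share of OPDA rises was 6 with the filter at 64, 3 with quantile normalization, 5 with the replicate block, 6 with the filter at 128 and 0 without the pair. The share of OPDA falls was 0, 8, 0, 5, 8, 0 and 7 with the filter at 64, quantile normalization, the variance trend, array weights, the replicate block, the filter at 128 and without the pair. The share of PPA1 falls was 24, 14 and 2 with quantile normalization, array weights and the filter at 128. Lists past the test were 1 for OPDA in the mutant and 1 for the genotypes with median centring, and 1 for the genotypes with the replicate block. With an estimated correlation they were 1, 1, 0, 0, 0, 0 and 0 for OPDA and PPA1 against OPDA in Col-0, OPDA and PPA1 against OPDA in the mutant, the genotypes and both genotype differences. With fry they were 5, 6, 1 and 0 for OPDA in Col-0 and the mutant and both genotype differences.

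Leaving out each array gave 351 to 622, 800 to 1001, 625 to 754, 361 to 630, 1019 to 1455, 559 to 748 and 43 to 86 probe sets in the same order. The counts were 0 to 7 for the PPA1 and 0 to 3 for the OPDA genotype difference, with shares of 58 to 93, 6 to 34, 4 to 26 and 0 to 17 (PPA1 rises and falls, OPDA rises and falls), overlaps of 114 to 161 and 37 to 72. Lists past the test were 2, 3 to 4, 3, 2, 1 to 3, 2 to 3, 0 to 3, 1 to 2 and 1 to 2 over the 9 comparisons. Of 198 such counts 145 stayed within 1.5 times, and of 2070 values of named genes 1775 kept their call. The check of TGA2, TGA5 and TGA6 was not run, as no value could be assigned to them. Probe sets near the background limit what can be seen, with 14.4% to 18.0% of intensities below 16 on each array.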

Other observations

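All tests on gene families and on genes that differ under every treatment were chosen after the annotation or the values were seen, except that the test of chromosome segments and the splits were fixed before their results. Groups of genes with a shared symbol prefix, called families here, added cell-wall and cytoskeleton genes, among others, to the lists. The rule goes by the letters of the symbol alone. GH can therefore pool unlike genes, since the auxin-conjugating gene GH3.3 bears that prefix too. With OPDA in Col-0, 2 of 5 beta-tubulin genes fell, TUB5 by a log2 difference of -1.18 and TUB1 by -1.06 (family median -0.70, camera adjusted p = 0.00107, and 0.0308 with an estimated correlation). Only 1 fell without Col-0 control replicate 1 or Col-0 OPDA replicate 2. Of 47 UGT glycosyltransferase genes 11 rose with OPDA in Col-0 and 2 fell, with a family median of 0.18 (adjusted p = 5.7e-04, and 0.0261 with an estimated correlation). With PPA1 in Col-0 the tubulin (-0.53), xyloglucan endotransglucosylase XTH (-0.93), TBL (-0.55) and GH (-0.75) families were lower. With PPA1 in the mutant the expansins (-0.71) and GH genes (-0.90) were lower and the autophagy genes (0.32) higher. These medians passed the preset test, and none passed with an estimated correlation, the adjusted p then being 0.143 to 0.365. The families PUB and XTH for OPDA in Col-0, and PUB, TUB and UGT for OPDA in the mutant, passed the preset test and not that with an estimated correlation. All of these medians kept their sign with median centring and quantile normalization. Fewer arrays ended some calls: for PPA1 in Col-0, GH without Col-0 control replicate 3 (0.0599) or Col-0 PPA1 replicate 1 (0.0905), TBL without Col-0 control replicate 3 (0.0599) or Col-0 PPA1 replicate 2 (0.0717), and TUB without Col-0 PPA1 replicate 1 (0.0595).

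For 210 probe sets the genotype difference averaged over the treatments passed the threshold and was at least 2-fold in the same direction under each of the 3 treatments, 119 higher and 91 lower in the mutant. Lower were GSTU25 (-4.49), AT5G16980 (-3.25), OCT5 (-3.20), AER (-2.48) and the glycosyltransferase gene UGT73B1 (-2.29), and, with a mean below 16 in at least 1 group of the mutant, URE, UGT73C1 and UGT73B4. Some of these averages cover unequal differences in control, with PPA1 and with OPDA. They were -2.41, -5.52 and -5.54 for GSTU25 and -1.19, -3.56 and -2.68 for AER. For AT5G16980 they were -1.82, -5.10 and -2.82, and for OCT5 -2.34, -4.20 and -3.05. Such averages mix a difference in control with a difference of the response. Higher were AT5G03350 (3.35), ECS1 (2.86), AT2G25510 and the chitinase-like pair AT2G43610 (1.28) and AT2G43620 (1.56). Taken by treatment, 117 probe sets differed in control, 344 with PPA1 (151 higher, 193 lower) and 172 with OPDA (84 and 88).

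The mutant line might carry chromosome segments of another origin, which would place such genes next to each other. Of 109 of these genes among 12574 measured loci, 15 pairs lay within 10 loci of each other, where 10000 random gene sets gave a median of 9 and a 95th percentile of 15 (permutation p = 0.0539). Related genes in tandem, such as AER and AT5G16980, add to such pairs, so this test leaves the explanation open, and a segment cannot be told apart from clusters of related genes. AT5G06940, the locus beside AT5G06950 (TGA2), was lower in the mutant on average (adjusted p = 0.0295), with means of 69.0, 48.4 and 53.2 in the Col-0 groups and 19.3, 16.7 and below 16 in those of the mutant. In control plants it did not pass (adjusted p = 0.326), and its neighbours AT5G06930 and AT5G06970 differed by 0.0111 and -0.00148.

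For the comparisons of 3 arrays against 3, the 10 possible splits are too few for a share under 0.05. Every other split mixes arrays of both conditions, which adds their difference to the spread within groups. Low counts in those splits therefore do not show chance alone. The real counts of probe sets were 546, 1083, 781, 592, 1414, 780 and 117, each reached by 1 of 10 splits, and the highest other counts 4, 1, 3, 2, 1, 1 and 3, for PPA1, OPDA and PPA1 against OPDA in Col-0, the same in the mutant, and the genotypes in control. The real counts of lists were 2, 3, 3, 2, 2, 3 and 2 in that order, reached by 5, 2, 3, 1, 2, 1 and 1 splits, and the highest other counts 2, 3, 3, 1, 2, 2 and 1.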
